A study of Homo sapiens with 13 samples.

How the data were processed

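CUT&RUN, in which nuclease tethered by an antibody releases the bound DNA fragments, was carried out with 500 ng of an EZH2 antibody per reaction. Per the labels' protocols, 0.12 ng of E. coli DNA was spiked into each reaction and 6 ng of DNA went into each library. The 12 EZH2 libraries form 4 groups of 3, individual or dual-specificity aptamers in Wnt- or Wnt+ medium, and groups and replicate numbers come from the labels. The IgG control sample (n = 1) was not analysed here as a sample of its own.

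Per the submitters' processing notes, Trim Galore, Bowtie2, SAMtools, bedtools, SEACR, DiffBind and ChIPseeker were used, with the builds GRCh38.p13 for human and ASM584v2 for E. coli. Their versions, order and parameters are not given in the sources used here. The deposited lists have the 6 columns of SEACR output and hold peaks called by the authors per library, with the stringent setting against IgG as named by the files. Replicates were not pooled. The value columns used are the authors' signal, summed over the peak and at its maximum. In each library the maximum was a whole multiple of 1 value within 0.01 for all peaks, from 0.869 to 4.69 signal units per step, so that coverage had been multiplied by 1 factor per library. The summed signal divided by that factor was whole within 0.05 bp for 96.3% to 100% of peaks. The formula of the factor is not given in the sources used here. A step was taken as 1 fragment. The lowest summed signal was 4818.9 to 4823.62 in 9 libraries and 4321.27 to 4323.7 in 3, called here the libraries with the lower calling floor. Because peaks are called against a floor on scaled signal, both the factor and the depth can set how many peaks a list holds. Signal was used only to rank or filter peaks within a library.

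Peaks on chromosomes 1 to 22 and X were kept, and 140 peaks on other contigs were left out. Peaks of the 12 libraries that overlapped by at least 1 bp were merged into regions, and a library held a region when at least 1 bp of it lay in one of its peaks. Positions are 1-based. Genes were the protein-coding genes of the RefSeq table of GRCh38.p14, a later patch of the same assembly, used for names and for which peaks neighbour which genes. The planned promoter window was 2 kb each side of a transcript start. The table gives no strand, so a window of 2 kb each side of both annotated gene ends was used in its place, and a peak there can lie at the start or at the end of a gene. A gene sharing a region with a neighbour cannot be told from it.

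The number of peaks was compared on the log2 scale with two-sided exact permutation tests, over 20 arrangements for 3 against 3 libraries and 400 within strata for the pooled comparisons, with a smallest p of 0.1 and 0.005. Regions and gene windows held by 5 to 7 of the 12 libraries, which alone can reach p under 0.05, were tested with a two-sided Fisher's exact test of 6 against 6 libraries and Benjamini-Hochberg adjustment. Regions held by 3 of 3 against 0 of 3 libraries were counted, with no p per region. The percent of each of 18 gene lists with a peak was compared with exact permutation tests within strata, and enrichment among bound genes with a one-sided Fisher's exact test. All fixed members matched the table except 1 Polycomb subunit. Overlap of lists was tested with 100000 permutations of group labels. The tests, lists and the rule for named genes were set before the data were examined. The rule took up to 4 members of each list with a peak in at least 3 libraries, up to 10 genes per direction of each comparison held by 3 of 3 against 0 of 3 libraries (filled to 5 by weaker differences), the 10 leading genes held in all 12 libraries, genes past a test, and CTNNB1, EZH2, OGT, OGA and AXIN2. Some genes that the rule names are not reported here.

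The region test was tested on simulated data with 15683 regions, 200 of them changed. Of regions held by all libraries of one side and none of the other, 100% were recovered in both pooled comparisons, which needs many such regions at once. With 2 or 10 of them planted 0 were recovered, and with 50 all 50 were, in each comparison. At 90% against 10% holding, 25.5% were recovered for the aptamer comparison and 33.0% for the medium comparison, and at 75% against 25% none were, with 0 false calls. Planted regions had the same chance of being held in each library of a side, whatever the length of its list. The real libraries held 265 to 9707 regions, so recovery in these data may be lower. Interval code gave the same results as bedtools 2.31.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

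Alternatives planned before the data were examined were the higher-signal peaks of each list (the upper 50%), an equal number of 276 peaks per library by total or maximum signal, covered length, all contigs, peaks of at least 500 bp, merging within 1 kb, 50% cover, windows of 1 and 5 kb, the replicate number as a block and each library left out in turn. Alternatives added after seeing the data were a common floor on scaled signal (4823.62), a common floor on unscaled coverage (5547 bp), the whole gene with 2 kb each side, and leaving out the 3 libraries with the lower calling floor. Percent differences of all 18 lists were followed under the alternatives. This extent was also set after seeing the data, at first with fewer lists.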

Results

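Binding of EZH2, the catalytic subunit of Polycomb repressive complex 2, was profiled by CUT&RUN in HEK293T cells, a human embryonic kidney cell line. The cells stably carried a shRNA against β-catenin, the transcriptional effector of canonical WNT signalling. They were transfected with individual aptamers, which served as the control, or with a dual-specificity aptamer designed to raise O-GlcNAc, a single-sugar modification, on β-catenin. Each was combined with regular medium (Wnt-) or with 50% Wnt3A-conditioned medium for the last 4 hr (Wnt+), and cells were harvested 24 hr after transfection. The 4 groups held 3 libraries each. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

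The 12 peak lists held 25585 peaks on chromosomes 1 to 22 and X, which merged into 15683 regions. Of these regions, 12614 (80.4%) were held by 1 library, 639 by at least 6 and 114 by all 12. The median width of the 114 shared regions was 3357.5 bp. Read depth is unknown from the lists. The median peak summit corresponded to 4 to 17 stacked fragments per library, as recovered from the steps of the signal.

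Of 19970 protein-coding genes, 6264 had a peak within 2 kb of an annotated gene end in at least 1 library, and 92 had one in all 12. Ranked by the percentile of total signal within each library, PTCHD1 came first (mean percentile 99.8; chromosome X, 23331135 to 23337425, GRCh38.p13, as for all positions given here). It was followed by TMEM132E (99.7; chromosome 17, 34578153 to 34583255), the adhesion receptor gene ADGRB1 (99.6; chromosome 8, 142448893 to 142453479) and VSTM2B (99.4; chromosome 19, 29524038 to 29530962). The progesterone receptor gene PGR (99.3; chromosome 11, 101126502 to 101130575) and the growth factor gene FGF3 (99.2; chromosome 11, 69816229 to 69820145) came next. One region on chromosome 9, 137166149 to 137171015, served GRIN1, which encodes a subunit of the NMDA receptor, and its neighbours LRRC26 and TMEM210, and these 3 genes cannot be separated. PRDM12, a regulator of sensory neuron development, completed the 10 leading genes (98.6; chromosome 9, 130658767 to 130666236). Each of these regions overlapped an annotated end of its gene.

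Lineage transcription factors, the textbook targets of Polycomb repression, carried EZH2 in every group. A gene was taken as bound in a group when at least 2 of the 3 libraries had a peak in its window. Bound members numbered 26 of 124 with individual aptamers and 19 with the dual aptamer in Wnt-, and 13 and 20 in Wnt+. The odds ratios against other protein-coding genes were 3.92, 4.38, 7.68 and 7.79 (one-sided Fisher's exact test, highest adjusted p = 8.19e-06 over 18 lists and 4 groups). NKX6-2 and NKX2-2, regulators of neural tube patterning, IRX4 and LHX3 had a peak in all 12 libraries. The NKX6-2 region spanned 132786136 to 132789928 on chromosome 10. Genes are not independent replicates, so these tests describe the lists and not the conditions.

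Neuronal genes were also enriched in each group. In Wnt-, 9 of 32 were bound with either aptamer treatment, and in Wnt+ 8 were. The odds ratios for individual and dual aptamers were 5.73 and 9.39 in Wnt- and 21.6 and 13.2 in Wnt+ (highest adjusted p = 0.00106, Fisher's exact test). Of the other genes, 6.39% and 4.00% were bound in Wnt- and 1.52% and 2.46% in Wnt+. With 276 peaks taken from each library by total signal, the odds ratios over the 4 groups were 22.7 to 28.8. The difference in odds ratio between groups was not tested. The examples with a peak in all 12 libraries were GRIN1, the potassium channel gene KCNA1, the neurotrophin receptor gene NTRK3 and SLC32A1, the vesicular GABA transporter gene. Ligands of the BMP, TGF-beta, FGF and hedgehog families were also enriched in the 4 groups, with 7, 6, 5 and 4 of 30 bound in the order above (Fisher's exact test, adjusted p = 0.0126, 0.00612, 0.000826 and 0.0267). FGF10 and SHH had a peak in 11 libraries each and GDF7 in 9. With 276 peaks taken from each library by total signal, this list passed the threshold in 3 of the 4 groups. Its odds ratios over the 4 groups were then 8.31 to 13.5, against 4.45 to 12.8 with all peaks.

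Genes of the WNT pathway were among the bound genes. The ligand gene WNT7A had a peak in all 12 libraries (chromosome 3, 13877378 to 13881539) and WNT3A in 8. The receptor gene FZD8 had one in all 12 and FZD4 in 8. Secreted WNT antagonists passed the enrichment threshold with the dual aptamer in Wnt-, with individual aptamers in Wnt+ and with the dual aptamer in Wnt+ (4, 3 and 4 of 19 bound; Fisher's exact test, adjusted p = 0.0267, 0.0145 and 0.00612), and with individual aptamers in Wnt- 3 of 19 were bound (adjusted p = 0.39). NOTUM, a secreted WNT deacylase gene and itself a β-catenin target, had a peak in 11 libraries, SFRP5 in 10 and KREMEN2 in 9. KREMEN2 encodes a membrane receptor, so the list does not hold secreted proteins only. WNT ligands (5 of 19 bound, Fisher's exact test, adjusted p = 0.00555) and β-catenin/TCF target genes (7 of 40, adjusted p = 0.00612) passed with the dual aptamer in Wnt- and missed the threshold in the other 3 groups, and the difference between groups in this enrichment was not tested. These calls for antagonists, ligands and targets were all lost when 276 peaks were taken from each library by total signal. The odds ratios over the 4 groups were then 5.54 to 6.66 for ligands, against 1.71 to 8.53 with all peaks, 0 to 6.66 for antagonists, against 2.74 to 12.0, and 0 to 3.07 for targets, against 1.62 to 5.07.

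The other lists did not pass the enrichment test in any group. Of the 39 HOX genes, at most 1 was bound in a group, and HOXB9, the member found most often, had a peak in 4 libraries. No liver, gut or muscle gene had a peak in any library. Replication-dependent histone genes were not bound in any group, and clustered protocadherins numbered 2 of 53 at most. Constitutively transcribed genes were bound at 2 of 42 or fewer, with LDHA and PCNA in 4 libraries each. Core WNT pathway components reached 4 of 32 bound, Polycomb subunits 2 of 30, the O-GlcNAc and hexosamine pathway 1 of 12, tumour suppressor loci 1 of 17, blood and immune genes 1 of 20 and kidney epithelial genes 1 of 18. In these lists CDKN1C had a peak in 8 libraries, IKZF1 in 6 and SALL1 in 9. Of the genes the design is about, CTNNB1, EZH2 and OGT had no peak in their windows in any library. OGA, the gene of the enzyme that removes O-GlcNAc, and AXIN2, a β-catenin target, had one in 1 library each.

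**Figure D1:**
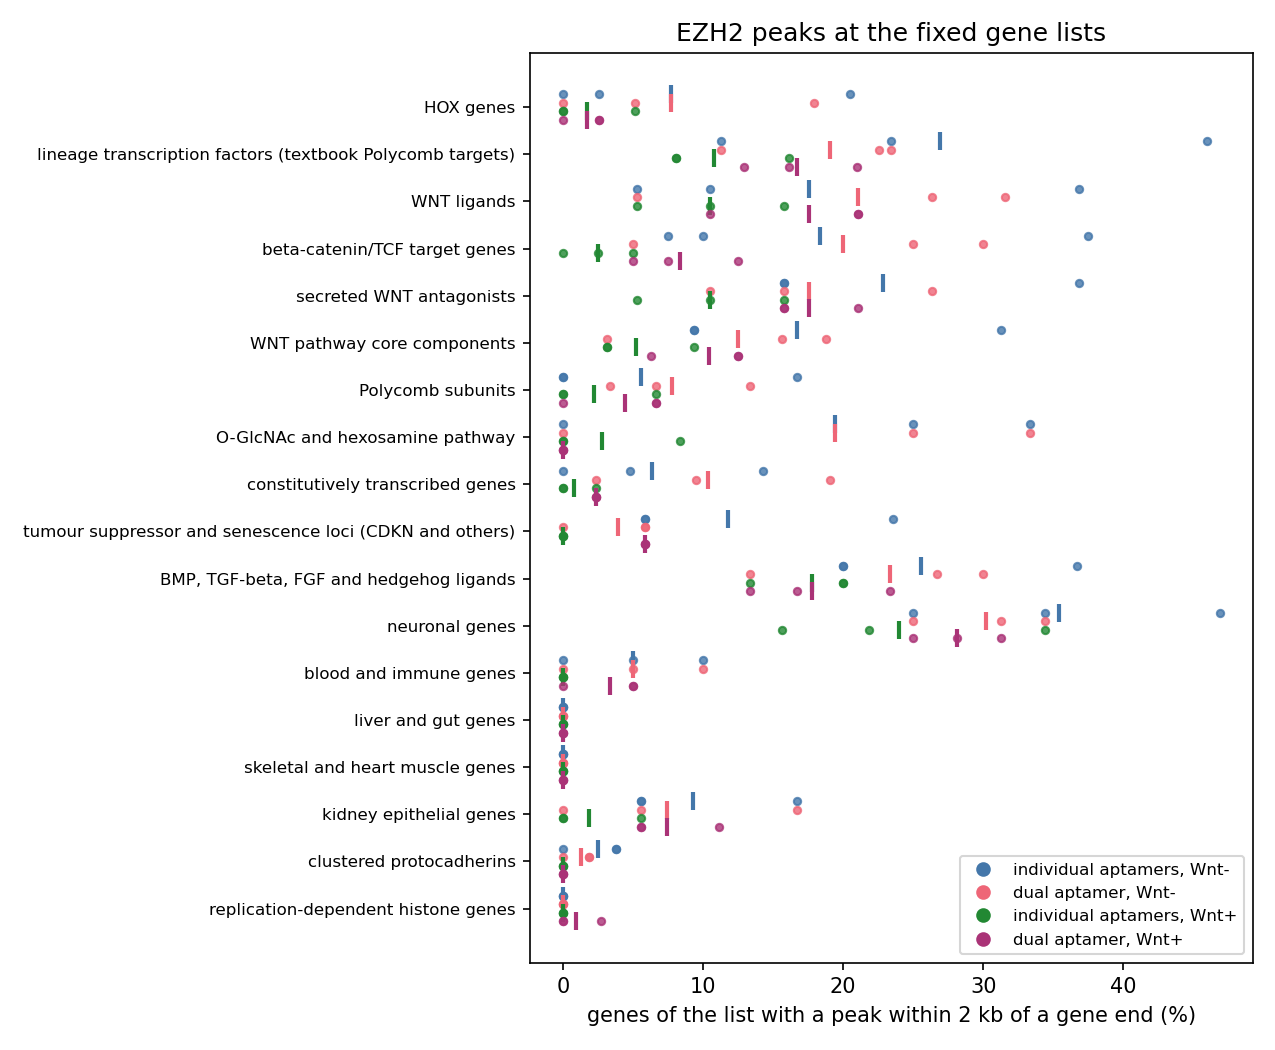
Percent of the genes of each of the 18 lists with an EZH2 peak within 2 kb of an annotated gene end (x axis), with 1 point per library, a vertical bar at the mean of each group of 3 libraries and colours for the 4 groups. Neuronal genes had the highest mean percent in each group, from 24.0% with individual aptamers in Wnt+ to 35.4% with individual aptamers in Wnt-.

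The first comparison asked whether the dual-specificity aptamer altered EZH2 binding. In Wnt-, libraries with individual aptamers held 2603 ± 2403 peaks (SD, n = 3) and those with the dual aptamer 4059 ± 5108 (SD, n = 3). In Wnt+ the numbers were 753 ± 416 (SD, n = 3) and 1113 ± 389 (SD, n = 3), with 276 to 1041 and 840 to 1559 in single libraries. The ratio of geometric means was 1.07 in Wnt- (two-sided exact permutation test, p = 1) and 1.66 in Wnt+ (exact p = 0.6), where 3 against 3 libraries allow no p below 0.1. The ratio in Wnt- (log2 0.09) turned direction for covered length (-0.0259), peaks of at least 500 bp (-0.13), a common scaled floor (-0.10), a common unscaled floor (-1.24) and without replicate 2 of the dual aptamer group (-1.07) or replicate 3 of the individual aptamer group (-0.70). Over both media the ratio was 1.33 (exact permutation test within media, p = 0.615). Without replicate 2 of the dual aptamer group in Wnt-, which alone held 9896 peaks, the pooled log2 ratio was -0.17 in place of 0.41. The difference between the 2 aptamer effects did not pass its own test (log2 difference 0.63, exact p = 0.745), and this value turned to -0.50 without replicate 3 of the dual aptamer group in Wnt- and to -0.13 without replicate 2 of the individual aptamer group in Wnt-.

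**Figure D2:**
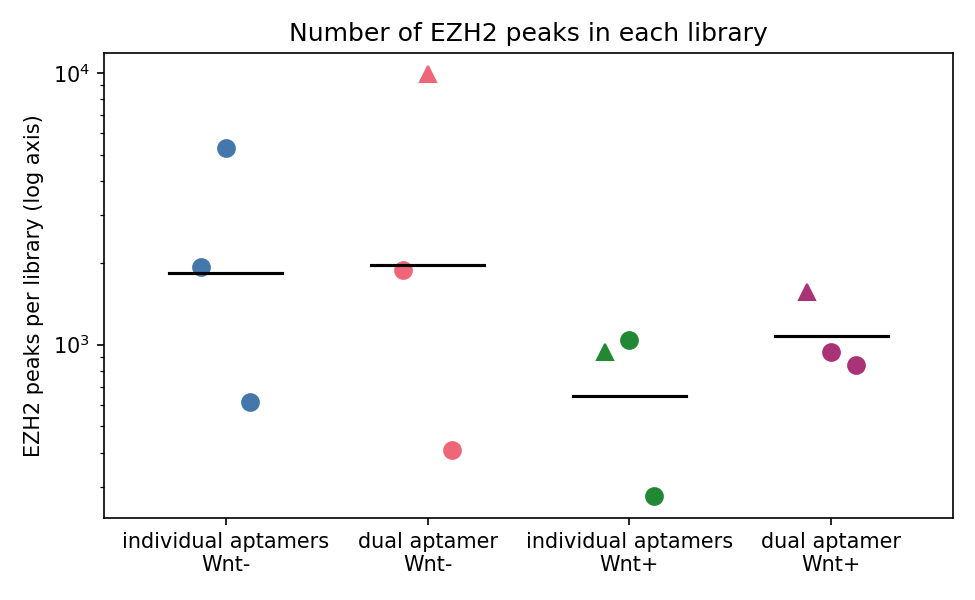
Number of EZH2 peaks in each library on a log axis, with 1 symbol per library, a bar at the geometric mean of each group and triangles for the 3 libraries whose lists reach down to a lower total signal. The 12 libraries range from 276 to 9896 peaks, and the groups overlap.

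At single genes, 13 had a peak in 3 of 3 libraries with individual aptamers and in 0 of 3 with the dual aptamer in Wnt-, and none showed the opposite. They included GPR149 (chromosome 3, 154427375 to 154429581), the adhesion gene KIRREL3, the ketone body enzyme gene OXCT1 and the ATP synthase subunit gene ATP5F1E. In Wnt+, 5 genes had a peak in 3 of 3 dual aptamer libraries and in 0 of 3 with individual aptamers, among them the cell cycle inhibitor gene CDKN1C, the transcription factor gene SOX14, LRRC10B and ANTXRL, and none the opposite. Of regions, 0 were held only with the dual aptamer and 16 only with individual aptamers in Wnt-, against 10 and 1 in Wnt+. With 276 peaks per library by total signal they were 2 and 3 in Wnt-, and 0 with the dual aptamer in Wnt+. Without the 3 libraries of the lower calling floor they were 2 and 29 in Wnt-, and 82 and 5 in Wnt+. These counts rest on groups reduced to 2 libraries, except individual aptamers in Wnt-, which kept 3. A smaller group is held in full, or lacks a region in full, more easily. Leaving out 1 library at a time, the 0 in Wnt- ran up to 63 (without replicate 3 of the dual aptamer in Wnt-), the 16 up to 358 (without replicate 3 of individual aptamers in Wnt-), the 10 up to 86 (without replicate 2 of individual aptamers in Wnt+) and the 1 up to 19 (without replicate 3 of individual aptamers in Wnt+). A region with 3 holding libraries among 6 falls on 1 such split in 10 by chance. Other splits of the 6 libraries gave up to 253 regions in Wnt- and 98 in Wnt+, with medians of 14 and 8. The real splits gave 16 and 11, both directions together. Over both media, 0 of 455 regions and 0 of 366 gene windows passed Fisher's exact test after adjustment, and 0 of each had an unadjusted p under 0.05. Adjusted over the list alone, 0 of the 21 testable members passed in the 8 lists that had any, and the other 10 lists had no member to test. The percent of list members with a peak did not pass for any list (exact permutation test within media, adjusted p = 1 for each). It was 17.9% with the dual aptamer against 18.8% with individual aptamers for lineage transcription factors, 14.2% against 10.4% for β-catenin/TCF target genes, 19.3% against 14.0% for WNT ligands and 9.72% against 11.1% for the O-GlcNAc and hexosamine pathway. Directions turned under alternatives. The difference for lineage transcription factors, -0.941 points, was 0.134 to 0.538 in 5 settings and -4.84 to 3.83 when 1 library was left out (without replicate 3 and without replicate 2 of individual aptamers in Wnt-). That for WNT ligands went from 5.26 to -5.26 with a common floor on unscaled coverage, and that for the O-GlcNAc and hexosamine pathway ran from -6.25 to 3.47 when 1 library was left out (without replicate 3 of individual aptamers and without replicate 3 of the dual aptamer in Wnt-).

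The second comparison asked how EZH2 binding differed after exposure to Wnt3A-conditioned medium. The geometric mean of peak number in Wnt+ was 0.352 times that in Wnt- with individual aptamers (exact permutation test, p = 0.3) and 0.546 times with the dual aptamer (log2 ratio -0.87, exact p = 0.7). With individual aptamers, single libraries held 276 to 1041 peaks in Wnt+ and 613 to 5273 in Wnt-. With the dual aptamer the direction turned without replicate 2 in Wnt- (log2 ratio 0.29), with a common floor on unscaled coverage (0.78) and without the 3 libraries of the lower calling floor (0.024). Over both aptamer treatments the ratio was 0.438 and did not pass its test (log2 ratio -1.19, exact permutation test within aptamers, p = 0.19). Above the unscaled floor, libraries with individual aptamers held 20, 663 and 252 peaks in Wnt+ and 178, 1058 and 193 in Wnt-. Those with the dual aptamer held 48, 941 and 305 in Wnt+ and 407, 47 and 143 in Wnt-. The lower number in Wnt+ thus depends on the floor, which itself works against libraries with a high factor. The SD of log2 peak number within groups ran from 0.47 to 2.30. Leaving out replicate 3 of the dual aptamer group in Wnt-, the library with 408 peaks, gave a log2 ratio of -1.76 (exact p = 0.035), and leaving out replicate 2 of that group gave -0.61.

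At 13 gene windows, more Wnt- than Wnt+ libraries had a peak at an unadjusted p under 0.05, and none went the other way. POLA1, the gene of the catalytic subunit of DNA polymerase alpha (chromosome X, 24692982 to 24694295), and PRXL2B (chromosome 1, 2585724 to 2587435) had a peak in 6 of 6 Wnt- libraries and 0 of 6 Wnt+ libraries (Fisher's exact test, p = 0.00216, adjusted p = 0.396 over 366 windows). SOX21, a neural transcription factor gene, had one in 6 of 6 against 1 of 6, and GPR153, PCNX2, MAP3K21, MYO10, CDK19, AMD1, HR, HRURF, ZNF438 and STX3 in 5 of 6 against 0 of 6 (Fisher's exact test, p = 0.0152, adjusted p = 0.427 for each). PCNX2 and MAP3K21 share 1 region, as do CDK19 and AMD1, and HR and HRURF, so the genes of each pair cannot be separated. Most of the 13 genes were chosen after their values were seen, since the naming rule covered POLA1, PRXL2B, SOX21, HR and ZNF438. Among regions, 11 of 455 had an unadjusted p under 0.05, all held more often in Wnt-, and 0 passed after adjustment (Fisher's exact test, lowest adjusted p = 0.492). With 276 peaks from each library, 0 regions by total signal and 1 by maximum signal had an unadjusted p under 0.05 for this comparison. With a common floor on unscaled coverage 0 had. Without the 3 libraries whose lists reach a lower total signal 30 had one, with 0 past adjustment in each of these settings. That last test set 4 Wnt+ against 5 Wnt- libraries. Other counts of holding libraries then reach such a p, so the 30 cannot be set against the 11.

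**Figure D3:**
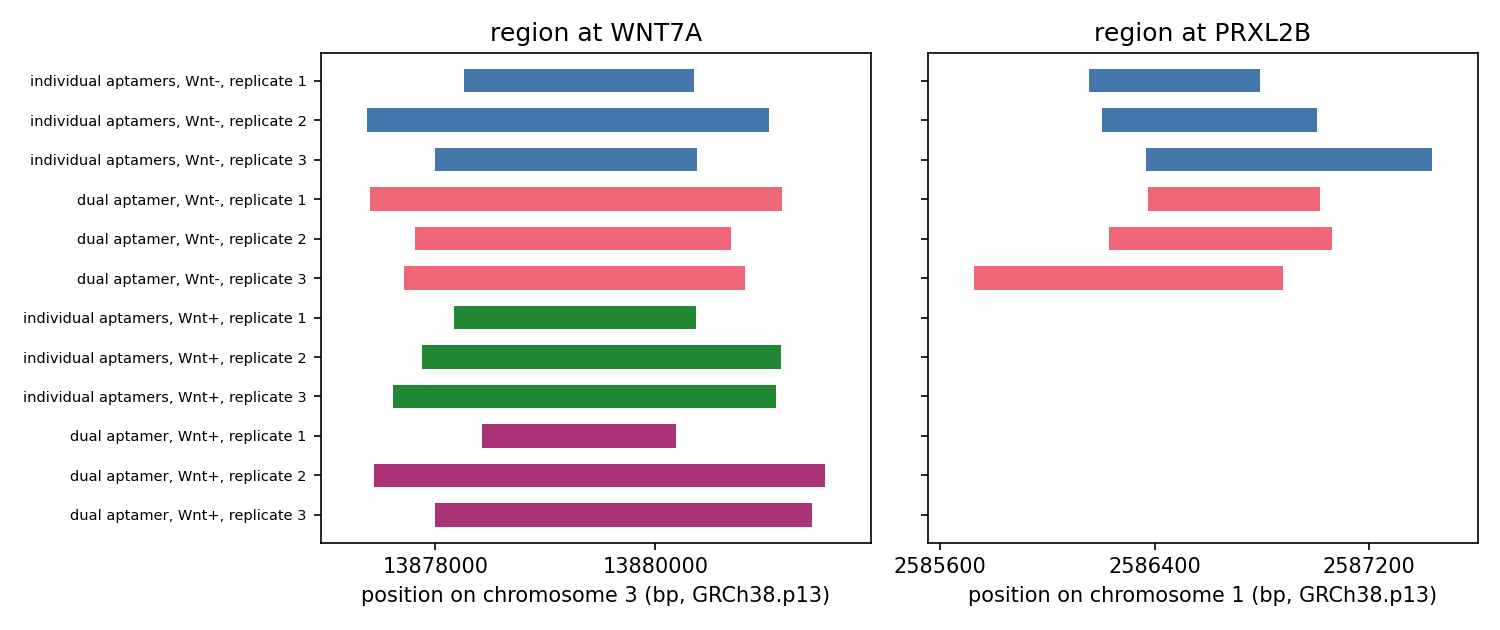
Peaks of the 12 libraries (1 bar per peak, from its start to its end, coloured by group) in the region at WNT7A on chromosome 3 and the region at PRXL2B on chromosome 1, with the x axis in bp of GRCh38.p13. The WNT7A region holds a peak in all 12 libraries and the PRXL2B region in the 6 Wnt- libraries.

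With individual aptamers, 55 genes had a peak in 3 of 3 Wnt- libraries and in 0 of 3 Wnt+ libraries, and none the opposite. Examples were the neurokinin receptor gene TACR1, the postsynaptic scaffold gene DLGAP1, the proneural factor gene NEUROG2 and ASCL2, a β-catenin target. ASCL2 had a peak in 2 of 3 dual aptamer libraries in both media. With the dual aptamer, 12 genes had a peak in 3 of 3 Wnt- and 0 of 3 Wnt+ libraries, among them the phosphodiesterase gene PDE4B, the lactate dehydrogenase gene LDHA and IGFBP7. The opposite held for 3 genes, among them SOX14 and the potassium channel gene KCNS2. Of regions, 57 were held only in Wnt- and 0 only in Wnt+ with individual aptamers, and 16 and 4 with the dual aptamer. The 57 became 2 with 276 peaks per library by total signal, 7 by maximum signal and 1 with a common floor on unscaled coverage, and up to 698 when 1 library was left out (replicate 3 of individual aptamers in Wnt-). Without the 3 libraries of the lower calling floor the direction turned with the dual aptamer, to 27 only in Wnt- and 48 only in Wnt+. These come from 2 libraries per group, which are held in full, or lack a region in full, more easily. Leaving out 1 library at a time, the 16 ran up to 253 (without replicate 3 of the dual aptamer in Wnt-) and the 4 up to 35 (without replicate 1 of the dual aptamer in Wnt-). In both directions together the real splits gave 57 and 20 regions. Other splits of the same 6 libraries gave up to 192 and 73, with medians of 7 and 16. With individual aptamers 2 of the 10 splits, the real one included, gave as many.

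The percent of list members with a peak was lower in Wnt+ for 15 of the 18 lists, and no list passed after adjustment. It was also lower for all protein-coding genes. These stood at 2.47% with individual aptamers and 3.26% with the dual aptamer in Wnt+, against 9.79% and 8.14% in Wnt-. The fall in a list was not tested against that of all genes. β-catenin/TCF target genes stood at 5.42% in Wnt+ against 19.2% in Wnt- (exact permutation test within aptamers, p = 0.05, adjusted p = 0.36 over 18 lists). Single libraries ran from 0% to 12.5% in Wnt+ and from 5% to 37.5% in Wnt-. The O-GlcNAc and hexosamine pathway stood at 1.39% against 19.4% (exact p = 0.08, adjusted p = 0.36), constitutively transcribed genes at 1.59% against 8.33% (p = 0.08, adjusted p = 0.36) and clustered protocadherins at 0% against 1.89% (p = 0.08, adjusted p = 0.36). Lineage transcription factors stood at 13.7% against 22.98% (exact permutation test, adjusted p = 0.45), neuronal genes at 26.0% against 32.8% (adjusted p = 0.473) and WNT ligands at 14.0% against 19.3% (adjusted p = 0.63). Directions turned under alternatives. With 276 peaks from each library by total signal, neuronal genes and WNT ligands were higher in Wnt+, by 0.521 and 1.75 percentage points. With a common floor on unscaled coverage 6 lists were, which were lineage transcription factors (0.269), neuronal genes (1.04), secreted WNT antagonists (2.63), Polycomb subunits (0.556), BMP, TGF-beta, FGF and hedgehog ligands (0.556) and kidney epithelial genes (1.85).

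The percent of peaks with a midpoint within 2 kb of a gene end was 69.7 ± 4.06 with individual aptamers and 56.3 ± 23.9 with the dual aptamer in Wnt-, and 60.5 ± 15.8 and 57.0 ± 17.3 in Wnt+ (SD, n = 3 each). The differences were -8.45 percentage points for the dual aptamer (exact permutation test within media, p = 0.3) and -4.26 for Wnt+ (exact p = 0.735). The first was -1.57 without replicate 2 of the dual aptamer group in Wnt- and -1.10 without the 3 libraries of the lower calling floor. The second was -11.1 without replicate 2 of the dual aptamer group in Wnt-, and its direction turned without replicate 1 of the dual aptamer group (0.735) or of the individual aptamer group (0.274) in Wnt+. The 3 lowest values, 28.8%, 37.0% and 42.4%, belonged to the 3 libraries with the lower calling floor, which were replicate 2 of the dual aptamer group in Wnt-, replicate 1 of the dual aptamer group in Wnt+ and replicate 1 of the individual aptamer group in Wnt+. The overlap of covered sequence had a mean Jaccard index of 0.174 within and 0.189 between groups (permutation test over group labels, p = 0.32). As a share of the shorter list it was 0.644 within and 0.623 between (permutation p = 0.54), so the direction turns with the measure.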

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

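The tests of peak number and of the 3-against-3 splits below were chosen only after the result was seen; those of the Wnt- regions and of single-library regions were set before it. Groups of 3 libraries are too small for a test of outlying samples.

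One region, on chromosome 8 from 26050250 to 26052635 and outside the nearest protein-coding gene EBF2, was held by 3 of 3 individual aptamer and 0 of 3 dual aptamer libraries in Wnt-, and by 0 of 3 and 3 of 3 in Wnt+. The difference was not tested. It was the 1 region of 15683 with this pattern, and 0 had the opposite one.

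The lists also held 140 peaks on 17 unplaced or unlocalized contigs, which enter only the peak numbers of the alternative with all contigs, with 2 to 36 per library and more than the 3 that a count of 0 allows in 11 of the 12 libraries. GL000225.1 and KI270467.1 held peaks in 11 libraries each.

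Peak number varied 35.9-fold between libraries and was highest in replicate 2 of the dual aptamer group in Wnt-. The aptamer as the source stays open. In Wnt-, replicate 3 of the dual aptamer group lies below every individual aptamer library, with 408 peaks against 613 or more, but 1 library decides nothing. The rule first written counted 1 such library against the aptamer. That rule, and the one for the factor below, were changed after their values had been seen. With a common floor on unscaled coverage, replicate 2 held 47 peaks, against a median of 222.5 over the 12 libraries and 1058 in the highest. Such a floor works against libraries with a high factor by construction, so this does not show the factor to be the source. Peak number rose with the factor over the 12 libraries (Pearson r = 0.70, permutation p = 0.0105, adjusted 0.0405; Spearman rho = 0.69, permutation p = 0.0158, adjusted 0.089; 6 relations computed) and fell with it above the unscaled floor (r = -0.69, permutation p = 0.0135, adjusted 0.0405; rho = -0.62, permutation p = 0.0347, adjusted 0.089), but without the 2 libraries farthest from the median factor r was 0.61 (permutation p = 0.0559, adjusted 0.0839) and above the unscaled floor -0.55 (permutation p = 0.0989, adjusted 0.119), so the relation rests in part on those. Among the 9 libraries with the higher floor r was 0.67 (permutation p = 0.0464, adjusted 0.0839; rho = 0.67, permutation p = 0.0589, adjusted 0.089) and above the unscaled floor -0.22 (permutation p = 0.552), the other 3 being too few. Whether the factor reflects spike-in recovery, depth or the amount of bound DNA stays open, since depth is not in the lists.

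The regions held in Wnt- and not in Wnt+ may come from the shorter Wnt+ lists. Every region's and every library's total was kept and the rest shuffled 500 times. With the observed data counted in, 14.0% reached the 11 regions seen, and the median of the shuffles was 7. Chance was not excluded either, since 17 of 100 drawn splits of the 12 libraries (462 possible) gave as many regions as the real 11. The other splits gave a median of 1 and up to 98. For gene windows 12 of 100 splits gave as many as the real 13, with a median of 1 and up to 76 in the others. What sets apart the splits giving several times the real count was not tested. Without the 3 libraries of the lower calling floor 11 of the 11 regions stayed at p under 0.05, but regions picked at this threshold could not have come out otherwise, so that this test decides nothing. An effect of the medium on these regions stays open.

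For the aptamer comparison, the real split gave 0 regions and 0 gene windows. Each of the 100 drawn splits reaches 0, so their number decides nothing. Other splits gave up to 104 and 59, with a median of 1 for each. For the 3-against-3 counts, 10 splits cannot give a share under 0.05. In both directions together the real splits gave 16, 11, 57 and 20 regions (aptamer in Wnt-, aptamer in Wnt+, medium with individual aptamers, medium with the dual aptamer). Of the 10 splits 5, 4, 2 and 4 were as large, the real one included. The other splits gave medians of 14, 8, 7 and 16 and up to 253, 98, 192 and 73.

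Of 12614 regions held by 1 library, 9499 (75.3%) came from the 3 libraries with the lower calling floor, which gave 48.5% of all peaks. Replicate 2 of the dual aptamer group in Wnt- alone gave 8128. Without it the other 2 gave 1371 of 4486 (30.6%), fewer than the 2405 of replicate 2 of the individual aptamer group in Wnt-, which has the higher floor. Only placement uniform over chromosome length is argued against. Near gene ends lay 14.9% to 19.6% of the single-library peaks of these 3, at least 3.28 times the 4.55% of chromosome length in such windows. The shared peaks of the same 3 libraries stood at 66.6% to 71.1%. The test cannot tell background calls from binding, since background need not be uniform. Coverage of few fragments remains a candidate explanation, as the median summit was 4 fragments for single-library and 5 for shared peaks in each of the 3, a difference of 1. Single-library peaks also had the lower median summit in the other libraries that held any, so the test does not separate the 3 from the rest. No biological explanation was tested for this pattern.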

How the results depend on the processing

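The common floors, the whole-gene window and the setting without the 3 libraries of the lower calling floor were chosen after seeing the data. Under the alternatives run, 0 regions and 0 gene windows passed Fisher's exact test and 0 lists the permutation test of list percents, which shows no stability, since these tests can hardly pass. With all 12 libraries, 20 of 455 regions or 16 of 366 gene windows would have to part the groups 6 against 0 for an adjusted p under 0.05, and 1 list alone cannot go below an adjusted p of 0.09. Lineage transcription factors and neuronal genes were enriched in 4 of 4 groups also with 276 peaks per library, with the upper 50% of peaks and with a common floor on unscaled coverage. Of all values under alternatives that answer a comparison, 402 kept their direction, side of the threshold or size within 1.5 times, 68 counts moved further, 20 values changed sign and 1 came past the threshold. The 402 include values that could hardly change, so the tally is no measure of stability. Among these are tests that can hardly pass, and 3-against-3 counts with a library outside the comparison left out. Where shorter lists or fewer libraries do not account for a change, the cause was not tested. Depth is unknown, and 4 to 17 fragments at the median summit limit what can be called.

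Pairing of the libraries by replicate number stays open. The correlations of deviations in 18 same-numbered pairs ran from -0.167 to 0.152, with a median of -0.0344 and 2 above 0.1. In 36 other pairs the median was 0.0142, also with 2 above 0.1. Both same-numbered pairs above 0.1 joined the 2 aptamer treatments in Wnt+ (replicates 1 and 2). Peak number in Wnt- had the same order over replicates 1, 2 and 3 with individual aptamers (1922, 5273, 613) and the dual aptamer (1874, 9896, 408). In Wnt+ the order differed (942, 1041, 276 and 1559, 941, 840). With the replicate number as a block, peak number over both media gave log2 0.41 for the aptamer (exact sign-flip p = 0.312) and -1.19 for the medium (p = 0.125), 0 regions and gene windows passed, and 2 regions and 2 gene windows had an unadjusted p under 0.05 for the medium. With the block the smallest p of a list is 0.03125, and 12 of the 18 lists would have to reach it, so the list counts under it decide nothing.

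The log2 ratio of peak number for the dual aptamer in Wnt-, 0.09 in the main setting, was -0.0259 for covered length, -0.13 for peaks of at least 500 bp, -0.10 with a common scaled floor, -1.24 with a common unscaled floor and -1.07 without the 3 lower-floor libraries. With the unscaled floor the medium with the dual aptamer gave 0.78 and the aptamer over both media -0.28, and without the 3 libraries these were 0.024 and -0.17. Overlap of lists as the share of the shorter list gave a within-group excess of 0.0211.

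Counts of regions held by all libraries of one group and none of the other are given for the dual aptamer and individual aptamers in Wnt-, then in Wnt+, then for Wnt+ and Wnt- with individual aptamers, then with the dual aptamer, and were 0 and 16, 10 and 1, 0 and 57, and 4 and 16. In the upper 50% of peaks, those that moved were 2 for individual aptamers in Wnt-, 0 for individual aptamers in Wnt+, 25 for Wnt- with individual aptamers, and 0 and 1 with the dual aptamer. With 276 peaks by total signal they were 2 and 3, then 0 for the dual aptamer in Wnt+, 2 for Wnt- with individual aptamers, and 2 and 1. By maximum signal they were 8 for individual aptamers in Wnt-, 4 and 0 in Wnt+, 7 for Wnt- with individual aptamers, and 2 and 0. With a common scaled floor, 2 were held in Wnt+ only with the dual aptamer. With the unscaled floor they were 1 for individual aptamers in Wnt-, 0 and 0 in Wnt+, 1 for Wnt- with individual aptamers, and 0 and 0. With 50% of the region covered they were 1 and 23 with individual aptamers and 2 for Wnt- with the dual aptamer. Without the 3 lower-floor libraries they were 2 and 29, 82 and 5, and 48 and 27 with the dual aptamer. Smaller groups are held in full, or lack a region in full, more easily. List and group pairs past the enrichment test numbered 17, and 11 with 276 peaks or the unscaled floor.

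At an unadjusted p under 0.05, the 11 regions and 13 gene windows of the medium comparison became 4 and 4 with the upper 50% of peaks, 0 and 0 with 276 peaks by total signal, 0 and 0 with the unscaled floor, and 30 and 31 without the 3 lower-floor libraries, and the regions 1 by maximum signal and 3 with 50% of the region covered. For the aptamer, 0 and 0 became 1 and 1 with 276 peaks by total signal and 9 and 8 without the 3 libraries. Without them other counts of holding libraries reach such a p, so these numbers cannot be set against those of 12 libraries.

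Differences in list percents, none past the threshold in any setting, changed sign as follows. For lineage transcription factors and the aptamer, -0.941 points became 0.134 with the upper 50% of peaks, 0.538 with 276 peaks, 0.269 with the unscaled floor, 0.269 with 5 kb windows and 0.403 with whole genes. For neuronal genes and the aptamer, -0.521 became 1.56 with the upper 50% of peaks, 0.521 with 5 kb windows and 1.56 with whole genes. WNT ligands and the aptamer went from 5.26 to -5.26 with the unscaled floor. Also for the aptamer, secreted WNT antagonists went from 0.877 to -2.63 with the upper 50% of peaks and -0.877 with the unscaled floor, and core WNT pathway components from 0.521 to -1.04 with the upper 50% of peaks, -2.08 with 276 peaks, -0.521 with the common scaled floor and -0.521 without the 3 lower-floor libraries. Kidney epithelial genes went from 1.85 to -1.85 with the upper 50% of peaks, -0.926 with 276 peaks and -0.463 without the 3 libraries, and BMP, TGF-beta, FGF and hedgehog ligands from -1.11 to 0.556 with 276 peaks. For the medium, WNT ligands became 1.75 and neuronal genes 0.521 with 276 peaks, and with the unscaled floor lineage transcription factors became 0.269, neuronal genes 1.04, secreted WNT antagonists 2.63, Polycomb subunits 0.556, BMP, TGF-beta, FGF and hedgehog ligands 0.556 and kidney epithelial genes 1.85.

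Leaving out each library in turn gave the ranges below. None is given for peak number with the aptamer in Wnt+ or the medium with individual aptamers, nor for list percents with the medium. The log2 ratio of peak number was -1.07 to 1.23 for the aptamer in Wnt-, -2.01 to 0.29 for the medium with the dual aptamer, -0.17 to 0.98 for the aptamer over both media, -1.76 to -0.61 for the medium over both aptamers and -0.50 to 1.80 for the interaction, with the ends set by replicates 2 and 3 of the dual aptamer group in Wnt-. Region counts, in the order above, were 0 to 63 and 16 to 358, then 10 to 86 and 1 to 19. For the medium they were 0 to 2 and 57 to 698, then 4 to 35 and 16 to 253. A group of 2 libraries is held in full, or lacks a region in full, more easily. Overlap within minus between groups was -0.0263 to 0.0019, and the difference in percent near gene ends for the medium -11.1 to 0.735. For the aptamer, list differences were -4.84 to 3.83 for lineage transcription factors, -3.13 to 2.34 for neuronal genes, -6.25 to 3.47 for the O-GlcNAc and hexosamine pathway, -1.32 to 4.39 for secreted WNT antagonists, -1.30 to 4.17 for core WNT pathway components, -2.45 to 1.96 for tumour suppressor loci, -2.78 to 1.67 for BMP, TGF-beta, FGF and hedgehog ligands and -0.463 to 3.70 for kidney epithelial genes.

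Of 99 named genes, the number of libraries with a peak stayed within 1.5 times for 90 with 1 kb windows, 94 with 5 kb windows, 96 with whole genes, 99 with the common scaled floor, 60 with the upper 50% of peaks, 31 with 276 peaks and 29 with the unscaled floor.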

Other observations

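The genes below were chosen after their values were seen. The 92 genes with a peak in all 12 libraries included those below, picked by hand and not a full list. CHAT and SLC18A3, which encode the enzyme that makes acetylcholine and its vesicular transporter, were both among them, as were the muscarinic receptor gene CHRM4, the glutamate receptor genes GRIK2, GRIK3, GRIN2C and GRM8 and the glutamate transporter gene SLC1A2. Potassium channel genes were KCNA3, KCNH5, KCNK12 and KCNQ3, and HCN4 encodes a pacemaker channel. Synaptic vesicle genes were SV2B, SYT10 and CPLX2, and RELN encodes the guidance protein reelin. Each of these genes had a peak in 12 libraries. CHAT and SLC18A3 share 1 region (chromosome 10, 49608410 to 49611598), and GRIN2C shares its region with FDXR (chromosome 17, 74858746 to 74862671), so that these genes cannot be separated from each other.

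Transcription factor genes in the same set included NEUROD2, NEUROG3, POU4F2, GSX1, DRGX, BHLHE22, ONECUT3 and EGR4 (mean percentile 96.8), and CYP26B1 encodes an enzyme that clears retinoic acid. The receptor tyrosine kinase genes RET and ALK and the WNT agonist gene RSPO3 were also held in all 12 libraries.

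A hypothesis drawn from these names was that ion channel or glutamate receptor families as such were over-represented. Of 282 symbol stems with at least 10 members, 0 passed a one-sided Fisher's exact test after adjustment. These stems split the potassium channels into subfamilies, and glutamate receptor stems had too few members to be tested. The stems with the lowest p were ADCY (2 of 10 members, ADCY2 and ADCY8, adjusted p = 0.26) and NKX (2 of 14, adjusted p = 0.26; Fisher's exact test). Whole families, grouped after the names and after the stems had been tested, gave 4 of 19 ionotropic glutamate receptor genes (adjusted p = 0.00044 over 284 families and stems) and 5 of 95 potassium channel genes (adjusted p = 0.011; Fisher's exact test). These 2 families were picked because their members had been seen in the set, so the p-values support no claim. Without the 7 genes that prompted the question, 1 of 16 and 1 of 91 were left (Fisher's exact test, adjusted p = 1 for both), which takes out the hits themselves and decides nothing either. The question needs other libraries, with both families fixed beforehand.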
